A study of Mus musculus with 13 samples.

How the data were processed

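RNA from mouse aorta was sequenced in 4 groups of animals: vehicle (4 samples), fasudil (3 samples), β-aminopropionitrile, here BAPN (3 samples listed), and BAPN with fasudil (3 samples). Per the labels' protocols, total RNA was extracted with TRIzol. The labels name 2 different instruments for the sequencing, so the instrument is not settled here. The submitters' processing notes name Bowtie2, RSEM and DESeq2 without versions or settings, and name the builds GRCm39 and mm10 without saying which step used which. The strand setting of the counting is not stated.

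The deposited table is titled as counts, but per the file headers and by its values it holds FPKM, fragment counts normalised to transcript length and to the library's mapped fragments, made by the authors and given to 2 decimals. It has 36082 rows, of which 28510 genes have values and 7572 rows have none. The authors also gave the mean FPKM of each group, which was used here only for checks. Another deposited column, the length of each gene's longest transcript in bases, is not a signal and served only to estimate depth. The gene coordinates were taken from the deposited table. Of 28343 genes whose identifiers are also in the GENCODE M21 annotation of GRCm38, 2.53% start at the same base, so positions are given as in the table, in GRCm39, and were not taken from GENCODE.

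The deposited column of BAPN replicate 2 equals BAPN replicate 1 plus 1 FPKM in all 28510 genes, so it is not a measurement of its own. The authors' BAPN group mean differed from the mean of the 3 deposited BAPN columns by more than 0.001 FPKM in 28495 genes. In each of the other 3 groups it differed in 0 genes. The BAPN replicate 2 column was therefore left out, before any test was run, and 12 libraries were analysed with 2 in the BAPN group. For all 28510 genes, exactly 1 value with 2 decimals for replicate 2 gives the deposited BAPN mean. That recovered library was analysed as an alternative chosen after seeing the data and after counts with it had been seen, and its values are named as such wherever they are printed.

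The values were scaled between libraries with a trimmed mean of log ratios, without weights, trimming 30% of the ratios and 5% of the mean levels at each end. Genes with at least 1 FPKM in at least 2 libraries were kept, which left 13748 genes. Changes were tested on log2 of scaled FPKM plus 1 with limma's moderated test with a mean-variance trend and robust prior variance. All 4 groups entered 1 fit with no covariate. P-values were adjusted by Benjamini-Hochberg in each comparison, and an adjusted p under 0.05 counted as a change. The test planned before the data were examined was a count model, with limma-trend on log2 of the value plus 1 as the stated substitute for normalized values. DESeq2 was not used here, because no counts were in the table. The scaling, the filter and the pseudocount for FPKM were set after the unit of the table was known and before any alternative was compared. Log2 fold changes of genes near 0 FPKM are reduced by the pseudocount.

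The comparisons were BAPN with fasudil against vehicle, against BAPN and against fasudil, each single treatment against vehicle, and the interaction, which is the fasudil effect with BAPN minus the fasudil effect without it. Before the data were examined, 27 gene lists and 17 lists of cell type markers were fixed, and the lists with at least 5 tested members (42) were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, directional and mixed, were run beside it. Members passing the threshold were counted over all genes and adjusted over the list alone. KEGG pathways were tested with a one-sided Fisher's exact test against the tested genes that the table assigns to any pathway, adjusted over 231 pathways. That enrichment was added after the data were seen.

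The rule for naming genes was also fixed before the data were examined. It takes genes past the threshold, without predicted-gene symbols, whose groups do not overlap and whose mean is at least 5 in the higher group. From these it takes the 12 with the highest and the 12 with the lowest log2 fold change in BAPN with fasudil against vehicle and against BAPN, 6 and 6 in the other pairwise comparisons, and 5 and 5 in the interaction. Where none qualified, the 3 genes with the smallest p are named. The lysyl oxidase genes, Rock1 and Rock2 are always named, and so are up to 4 members per list, or 2 where none passed. The minimum of 5 was written for CPM and applied here to scaled FPKM. Genes outside this rule are said to have been chosen after their values were seen. Loxl4 was below the filter and was not tested. Some genes and 1 gene list that this rule names are not reported here.

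The table gives no read counts. The steps between neighbouring FPKM values of transcripts of 300 to 900 bases, after subtracting 49 bases for the ends of a read, point to a depth of 20.4 to 20.9 M reads per library. This is an estimate. The agreement of the values with such steps, a mean cosine and not a share of values, was between 0.43 and 0.48 in each library. No counting intervals were computed. The tests were checked on simulated data for 13748 genes, with 100 genes changed by 1 log2 unit and 100 by 2. In the comparison of BAPN with fasudil against vehicle, 62% and 90% of these were recovered, with 11 false calls. For BAPN against vehicle the shares were 48% and 85% with 7 false calls. For fasudil against vehicle they were 68% and 97% with 3, for BAPN with fasudil against BAPN 47% and 87% with 6, and against fasudil 56% and 88% with 5. The simulated values varied independently between genes and with the same spread in every library, and only genes at higher levels were changed. The shares and false calls describe that setting and not the real libraries.

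Of the alternatives below, the recovered library with and without BAPN replicate 1, no scaling, both pseudocounts and the joint omission were chosen after seeing the data, the recovered library and no scaling after their counts had been seen. The alternatives tried were 2 other scalings and none, no filter and a stricter filter, library quality weights, only the compared groups in the fit, a prior variance that was not robust, pseudocounts of 0.1 and 5, a replicate block, an added minimum fold change, each library left out in turn, the recovered BAPN replicate 2 with and without BAPN replicate 1, and BAPN replicate 1 left out together with replicate 1 of BAPN with fasudil. The analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.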

Results

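Gene expression was measured by RNA sequencing in the aorta of mice given vehicle, fasudil, BAPN, or BAPN with fasudil. BAPN (β-aminopropionitrile) inhibits the lysyl oxidases that crosslink collagen and elastin, and fasudil inhibits the kinases encoded by Rock1 and Rock2. Fasudil was given in water at 150 mg/kg/day and BAPN at 0.25% in water. The mice had 1 week to acclimatise and 4 weeks of experiment, and animals of the combined group had BAPN alone for 1 week before fasudil was added. The labels call the combined treatment a model of aortic dissection, a tear within the aortic wall. The treatment arms held 11 mice for vehicle, 10 for fasudil and 12 for BAPN. The 12 libraries analysed came from 4 vehicle, 3 fasudil, 2 BAPN and 3 combined samples. Another BAPN column was left out because it repeats BAPN replicate 1 with 1 FPKM added. Values below are FPKM scaled between libraries, as mean ± SD with the number of libraries, and log2 fold changes (log2FC) carry their SE.

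The libraries held between 11127 and 13601 genes at 1 FPKM or more, at an estimated depth of 20.4 to 20.9 M reads. Genes placed on the mitochondrial chromosome, predicted genes such as Gm10925 among them, took 43.6% to 53.3% of all FPKM in the vehicle libraries. In the combined libraries they took 31.3% to 40.5%. With nuclear copies of mitochondrial genes added, the shares were 48.6% to 58.6% and 35.4% to 48.2%. Haemoglobin genes took 0.265% to 0.71% in vehicle and 1.35% to 3.45% in the combined group. Immunoglobulin genes took 10.5% of the FPKM of BAPN replicate 1 and at most 0.0456% in any other analysed library. The first principal component held 40.1% of the variance of the 500 most variable genes, and BAPN replicate 1 stood apart on it with a score of 60.8. That share was 32.2% without BAPN replicate 1. Genes with the lowest loadings on that component included Ucp1, Elovl3 and Otop1 of brown fat, and those with the highest included immunoglobulin genes and the sympathetic nerve genes Npy, Th and Dbh. The second component held 18.8% and ran from airway genes such as Scgb1a1 to the same nerve genes.

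**Figure D1:**
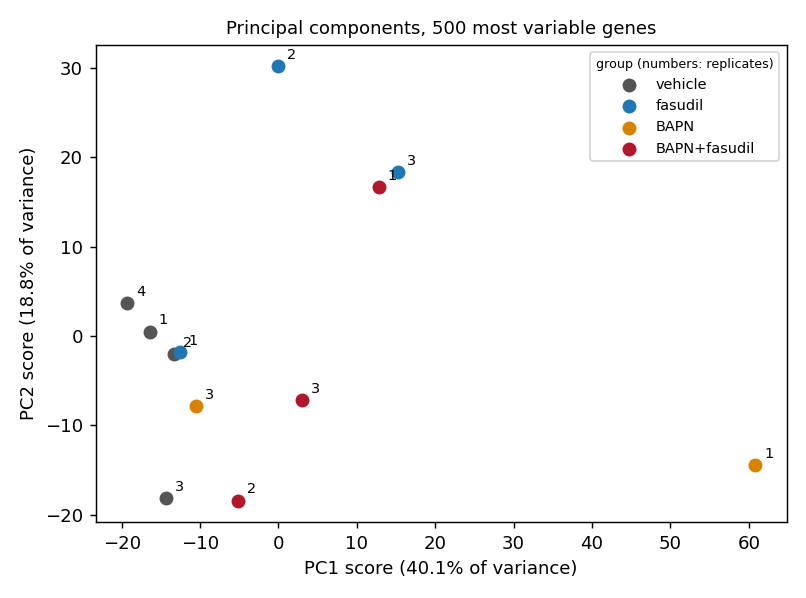
Scores of the 12 libraries on the first (x axis) and second (y axis) principal components of the 500 most variable genes, with 1 point per library, coloured by group and numbered by replicate. BAPN replicate 1 lies at 60.8 on the first component, and the vehicle libraries lie between -19.3 and -13.3.

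The comparison of BAPN with fasudil against vehicle asks how the aorta of the dissection model differs from that of mice given vehicle. The genes that fell included 3 of 15 brown adipocyte markers, and those that rose included 7 of 18 macrophage markers and 4 of 30 genes of matrix proteases and inhibitors, while 0 of 42 lists passed as a whole with an estimated correlation. Elovl3, an enzyme that elongates very long fatty acids, fell from 21.2 ± 12.9 (SD, n = 4) to 0.297 ± 0.0975 (SD, n = 3), with a log2FC of -3.87 ± 0.75 (SE). Thbs1, which encodes the matrix glycoprotein thrombospondin-1, rose from 1.68 ± 1.1 (SD, n = 4) to 19.5 ± 6.93 (SD, n = 3), with a log2FC of 2.96 ± 0.37 (SE). Timp1, an inhibitor of matrix metalloproteinases, rose from 6.68 ± 2.34 (SD, n = 4) to 88.8 ± 75.7 (SD, n = 3), with a log2FC of 3.27 ± 0.66 (SE), which was 2.61 without replicate 3 of the combined group (adjusted p = 0.0935). Limma's test called 231 of 13748 genes changed, 91 higher and 140 lower, and 3632 genes had an unadjusted p under 0.05. Thbs1 (ENSMUSG00000040152.9) lies on chromosome 2 at 117942357 to 117957614 in GRCm39, Elovl3 (ENSMUSG00000038754.6) on chromosome 19 at 46120336 to 46124133, and Timp1 (ENSMUSG00000001131.12) on chromosome X at 20736405 to 20740974.

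The 12 genes with the highest log2FC under the naming rule had adjusted p values between 0.0115 and 0.0439 by limma. As that rule requires, all 3 combined libraries lay above all 4 vehicle libraries for each of them. After Timp1 and Thbs1 they were Igfbp3 (2.52), which encodes an insulin-like growth factor binding protein, and Hmox1 (2.52, and 1.74 without replicate 3 of the combined group), the haem-degrading enzyme. Next came Wfdc17 (2.48), Fcer1g (2.32) and Mmp3 (2.26), of which Mmp3 encodes the matrix protease stromelysin-1. The others were Pgf (2.21), the placental growth factor, Gpnmb (2.18), Trem2 (2.12), Cthrc1 (2.06) and C1qb (2.04). Pgf rose from 1.56 ± 0.436 (SD, n = 4) to 11.4 ± 4.57 (SD, n = 3), and its adjusted p of 0.0115 was the lowest of the 24 named genes. The 12 genes with the lowest log2FC had adjusted p values between 0.0237 and 0.0496. After Elovl3 they were Ucp3 (-2.94), a mitochondrial carrier protein, Elovl6 (-2.94), Acaa1b (-2.53), S100b (-2.52) and Agpat2 (-2.50). They went on with Gys2 (-2.44), a glycogen synthase, Ehhadh (-2.32), an enzyme of peroxisomal fatty acid oxidation, Otop1 (-2.27), Acot11 (-2.23), the histone gene H4c8 (-2.19) and the desaturase gene Scd1 (-2.13). Agpat2, which acts in triglyceride synthesis, fell from 792 ± 173 (SD, n = 4) to 143 ± 56.6 (SD, n = 3).

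**Figure D2:**
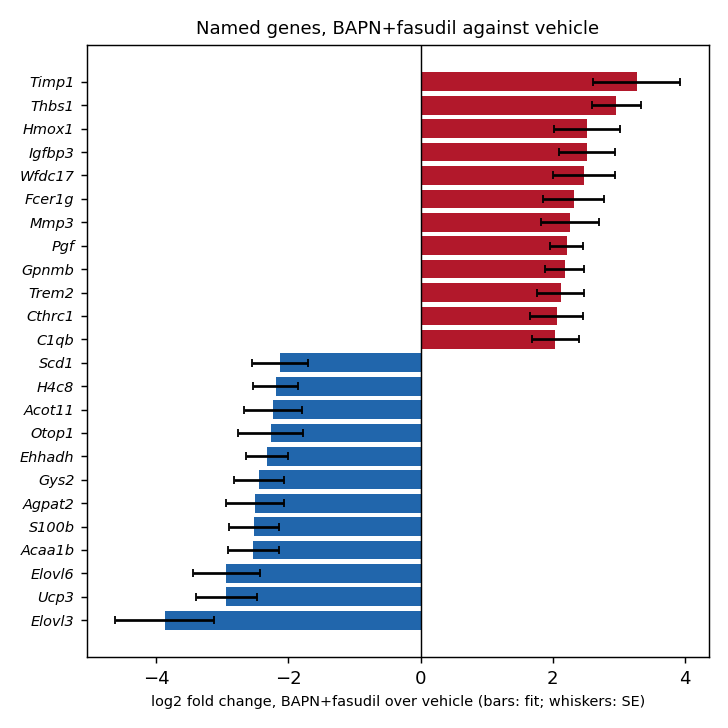
Log2 fold changes of the 24 named genes in BAPN with fasudil over vehicle (x axis, log2 units; 3 against 4 libraries), with 1 bar per gene and whiskers for the SE. Bars run from -3.87 for Elovl3 to 3.27 for Timp1.

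Among the lists of fat cell markers, 3 of 15 brown adipocyte genes fell (S100b, Elovl3 and Otop1) and none rose, with 11 lower when adjusted over the list alone and a median log2FC of -2.09. Its camera adjusted p was 2.14e-08, which became an adjusted p of 0.429 with an estimated correlation, and fry's adjusted p was 0.0304. Ucp1, the uncoupling protein of brown fat, was at 3460 ± 976 (SD, n = 4) with vehicle and 495 ± 44.3 (SD, n = 3) with the combination, and did not pass (log2FC -2.76 ± 0.83, limma adjusted p = 0.0792; chosen after its values were seen). Of 19 white and general adipocyte genes, Scd1 fell and Lep, which encodes leptin, rose (1.96 ± 0.40), with 9 lower and 1 higher when adjusted over the list alone and a median of -1. Adipoq, the adiponectin gene, had a log2FC of -0.41 ± 0.33 (adjusted p = 0.451). The adjusted p of that list was 2.71e-05, and 0.429 with an estimated correlation. None of 26 oxidative phosphorylation genes passed over all genes, while 26 were lower when adjusted over the list alone, with a median of -1.14 (camera adjusted p = 1.55e-13, and adjusted p = 0.429 with an estimated correlation). Of 13 mitochondrially encoded genes, mt-Nd3 fell (-1.48 ± 0.27), 11 were lower when adjusted over the list alone, and the list's adjusted p was 2.01e-06, or 0.429 with an estimated correlation. Hmgcs1 (-1.26 ± 0.20) and Insig1 (-1.28 ± 0.25), a synthase and a regulator of cholesterol synthesis, fell among 19 genes of that list, 3 of which were lower when adjusted over the list alone (median -0.15, camera adjusted p = 0.0752).

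KEGG pathways were tested on the same genes, a choice made after the data were seen, so they are not independent of the lists. Fisher's test also takes genes as independent of each other, which genes of the same pathway need not be. The peroxisome held 11 of the genes that fell among its 94 (adjusted p = 2.01e-06), fatty acid metabolism 7 of 50 (adjusted p = 0.000177) and the PPAR signalling pathway 7 of 81 (adjusted p = 0.00306), by a one-sided Fisher's exact test. Among the genes that rose, complement and coagulation cascades held 5 of 52 (adjusted p = 0.0258), namely F13a1, Plaur, Procr, Pros1 and Wfdc17.

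Of 18 macrophage genes, 7 rose and none fell, and 16 were higher when adjusted over the list alone. The median log2FC was 1.41. C1qb rose from 34.2 ± 4.78 (SD, n = 4) to 155 ± 77.6 (SD, n = 3), C1qc by 1.79 ± 0.34 on the log2 scale, Tyrobp by 2.01 ± 0.39 and the mannose receptor gene Mrc1 by 1.36 ± 0.25. The camera adjusted p was 2.36e-10, the adjusted p was 0.429 with an estimated correlation, and fry's adjusted p was 0.0278. C1qb and C1qc were also the 2 of 15 complement genes that rose, with 8 when adjusted over the list alone (median 0.93, camera adjusted p = 1.2e-05, and adjusted p = 0.429 with an estimated correlation). Gpnmb and Trem2 rose among 20 genes of lysosomes and lipid-laden macrophages, whose median was -0.10 while camera's direction was up (adjusted p = 0.668), with 6 higher and 4 lower when adjusted over the list alone. Of 26 cytokine and chemokine genes none passed, and 5 were higher when adjusted over the list alone. Their median was 0.85 (camera adjusted p = 4.9e-05, and adjusted p = 0.463 with an estimated correlation). No gene passed in the lists of neutrophils (median 0.76), T and NK cells (0.55), B and plasma cells (0.32), interferon response (0.21) or antigen presentation (0.58), and none of these 5 lists passed camera. The mast cell gene Kit rose (0.89 ± 0.18) among 6 genes with a median of 0.20 (camera adjusted p = 0.452).

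In the lists of extracellular matrix, 4 of 30 matrix protease and inhibitor genes rose, and 8 when adjusted over the list alone. They were Timp1, Mmp3, Mmp2 (1.74 ± 0.32), which encodes gelatinase A, and Plaur (1.72 ± 0.33), the urokinase receptor gene. That list had a median of 0.60 (camera adjusted p = 0.00262, and adjusted p = 0.429 with an estimated correlation). Thbs1 was the 1 gene that rose of 19 proteoglycan and glycoprotein genes, with 6 when adjusted over the list alone and a median of 1.13 (camera adjusted p = 2.71e-05, and adjusted p = 0.429 with an estimated correlation). Fst (1.75 ± 0.30), an activin antagonist, and Tgfb1 (1.05 ± 0.21) rose among 22 genes of TGF-beta and BMP signalling, with 7 when adjusted over the list alone and a median of 0.62 (camera adjusted p = 2.71e-05, and adjusted p = 0.429 with an estimated correlation). No gene passed among 19 collagens (median 0.78, and 1.46 without replicate 1 of the combined group), 16 elastic fibre genes (median 0.94) or 14 genes of lysyl oxidases and crosslinking (median 0.78). Over each list alone, 0, 2 and 4 of these were higher. Their camera adjusted p values of 0.000558, 0.00168 and 9.55e-05 became adjusted p values of 0.487, 0.487 and 0.429 with an estimated correlation. Col1a1 was at 85.9 ± 35.6 (SD, n = 4) with vehicle and 406 ± 192 (SD, n = 3) with the combination (log2FC 2.19 ± 0.69, adjusted p = 0.0846), and Eln, which encodes elastin, at 313 ± 125 and 2430 ± 2180 (2.34 ± 1.14, adjusted p = 0.221). Dpep1 rose (1.22 ± 0.25) among 16 adventitial fibroblast genes with a median of 0.88, 4 of which were higher when adjusted over the list alone (camera adjusted p = 5.2e-05, and adjusted p = 0.429 with an estimated correlation).

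The call for Lox, an enzyme target of BAPN, depended on the setting in this comparison. Lox was at 9.85 ± 2.99 (SD, n = 4) with vehicle and 47 ± 24.9 (SD, n = 3) with the combination, a log2FC of 2.02 ± 0.50 with an adjusted p of 0.0567 by limma. It passed in 6 of 14 other settings (adjusted p from 0.000761 to 0.298), and without BAPN replicate 1 (0.0188) or 3 (0.0194) of the 12 fits that left out a library. The log2FC was 0.78 for Loxl1, 0.86 for Loxl2 and 0.93 for Loxl3, with adjusted p values of 0.302, 0.191 and 0.256, and of 0.0113, 0.00756 and 0.00646 with library quality weights, the 1 of 14 settings in which they passed (highest adjusted p 0.594, 0.493 and 0.56). Rock1 (0.22 ± 0.16) and Rock2 (0.54 ± 0.16) had adjusted p values of 0.417 and 0.0741, and Rock2 passed in 4 of 14 other settings (adjusted p from 0.00334 to 0.316). In the contractile smooth muscle list 0 of 22 genes passed, also when adjusted over the list alone, with a median of 0.35 (camera adjusted p = 0.576). Acta2 (0.42 ± 0.94) and Tagln (0.58 ± 0.75), of the contractile apparatus had adjusted p values of 0.795 and 0.648.

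Further lists held single genes that passed. Adm, the adrenomedullin gene, rose (1.96 ± 0.36) and the glycolytic gene Pgk1 fell (-1.10 ± 0.22) among 20 hypoxia and glycolysis genes, with 3 higher and 7 lower when adjusted over the list alone (median -0.67, camera adjusted p = 0.1). Hmox1 was the 1 of 20 oxidative stress genes that rose (median 0.28, camera adjusted p = 0.453). Edn1, the endothelin-1 gene, rose (1.61) among 23 vasoactive genes (median 0.43, camera adjusted p = 0.013, and adjusted p = 0.487 with an estimated correlation). Of 28 ribosomal protein genes, 1 was higher over all genes and 20 when adjusted over the list alone (median 0.55, camera adjusted p = 2.36e-10, and adjusted p = 0.429 with an estimated correlation). The haemoglobin gene Hbb-bt rose (1.81 ± 0.35) among 8 red blood cell genes with a median of 1.79, and Gp1bb (1.44 ± 0.23) among 7 platelet genes with a median of 0.83. Their camera adjusted p values of 0.00168 and 0.00443 both became an adjusted p of 0.429 with an estimated correlation. No gene passed in the lists of serum response factor targets (median 0.63), cell cycle (0.36), immediate early genes (0.80) and endothelium (0.36), whose camera adjusted p values lay between 5.89e-05 and 0.0228 and became adjusted p values between 0.429 and 0.534 with an estimated correlation. With the preset correlation the cell cycle list did not pass without replicate 2 of the combined group (median 0.25), nor the endothelium list without vehicle replicate 3 or replicate 1 of the combined group (medians 0.21 and 0.29). Neither genes nor camera passed for p53 and apoptosis (median 0.37), unfolded protein response (0.24), circadian clock (-0.30), osteochondrogenic genes (0.55), skeletal muscle (0.60), cardiomyocytes (0.36) or epithelium (-0.62). In the nerve list (median 0.47, camera adjusted p = 0.453) the 1 gene that fell was S100b, also a brown adipocyte marker here. The lists of lymph node stroma (median 1.45, 3 genes) and of sex-linked genes (median -0.12, 4 genes) were too short to test.

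**Figure D3:**
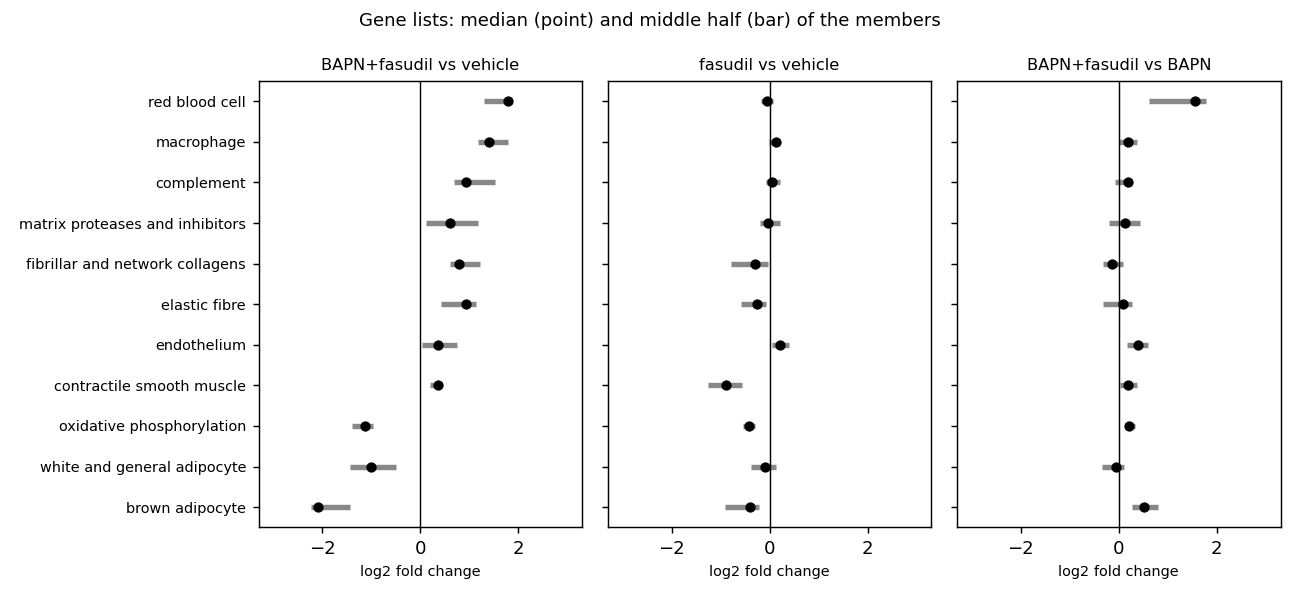
Median log2 fold change (point) and interquartile range of the members (bar) for 11 of the gene lists (y axis), in 3 comparisons (panels; x axis in log2 units). Against vehicle the brown adipocyte list lies at -2.09 and the macrophage list at 1.41, while in BAPN with fasudil against BAPN they lie at 0.51 and 0.19; none of these lists passed with an estimated correlation.

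The count of 231 was 1, 10, 48 and 3 without vehicle replicates 1 to 4, 13, 43 and 397 without fasudil replicates 1 to 3, 1695 and 1639 without BAPN replicates 1 and 3, and 16, 24 and 27 without replicates 1 to 3 of the combined group. The 24 named genes kept their direction in each of these 12 fits. The naming rule takes only genes whose groups do not overlap, so leaving out 1 library could hardly reverse them. Of the 24, 0 passed without vehicle replicate 1 or 4, 1 without vehicle replicate 2 or replicate 1 of the combined group, and 2 without its replicate 2. Without fasudil replicate 1 the number was 3, without replicate 3 of the combined group 8, and without vehicle replicate 3 or fasudil replicate 2 it was 9. Over all genes, 12 passed without the filter and 1680 without scaling, where the median of all genes lay at 0.35 rather than 0.06. More genes fell than rose among the 231, but without scaling 1452 were higher and 228 lower, and with library quality weights 2695 were higher and 2506 lower. The higher genes also outnumbered the lower ones without replicate 1 of the combined group (10 and 6), without its replicate 2 (17 and 7) and without vehicle replicate 1 (1 and 0).

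BAPN against vehicle asks what inhibiting the lysyl oxidases does alone. With 2 BAPN libraries limma called 0 of 13748 genes, 2832 had an unadjusted p under 0.05, and library quality weights also gave 0. The genes with the smallest p were Fbp2 (-2.19 ± 0.25), a fructose bisphosphatase, Gys2 (-3.23 ± 0.43) and Fam131c (-1.71 ± 0.23), with adjusted p values of 0.0693, 0.0738 and 0.0738. They passed in 4, 4 and 3 of 14 other settings. Leaving out either BAPN library leaves 1 in that group, with no spread of its own. Without BAPN replicate 3 the log2FC of these genes were -2.59, -3.8 and -1.82. Lox was at 61.7 ± 49.5 (SD, n = 2) with BAPN, against 9.85 ± 2.99 (SD, n = 4) with vehicle (log2FC 2.31 ± 0.57, adjusted p = 0.0943). Its log2FC was 1.4 without BAPN replicate 1 and 3.21 without BAPN replicate 3. The log2FC was 0.67 for Loxl1, 1.13 for Loxl2 and 0.94 for Loxl3, with adjusted p values of 0.495, 0.187 and 0.377. Over the list alone, 13 of 15 brown adipocyte genes were lower (median -2.19) and 11 of 18 macrophage genes were higher (median 1.36), and no member of either passed over all genes. Their camera adjusted p values of 3.61e-10 and 9.82e-10 both became an adjusted p of 0.538 with an estimated correlation. All 26 oxidative phosphorylation genes were lower when adjusted over the list alone (median -1.36, camera adjusted p = 6.92e-16, and adjusted p = 0.538 with an estimated correlation). B and plasma cell genes had a median of 1.59 and T and NK cell genes one of 1.12 (camera adjusted p = 0.000487 and 1.09e-05, and adjusted p = 0.538 for both with an estimated correlation). Without BAPN replicate 1 these medians were 0.15 and 0.12, and without BAPN replicate 3 they were 3 and 2.22. The cardiomyocyte, nerve and general adipocyte lists also passed camera, with medians of 0.78, 1.01 and -1.01 (adjusted p = 0.665, 0.665 and 0.607 with an estimated correlation). Without BAPN replicate 1 none of these 3 passed (medians -0.3, 0.08 and -0.12), nor did serum response factor targets, antigen presentation and cell cycle, whose medians went from 0.42, 0.58 and 0.43 to 0.09, 0.09 and -0.04. Without vehicle replicate 1, 2 or 4 the cardiomyocyte medians were 0.61, 0.73 and 0.58 and the nerve medians 0.66, 1.04 and 0.67, and neither list passed, nor did the nerve list without replicate 1 of the combined group. The brown adipocyte and oxidative phosphorylation medians were -1.46 and -0.57 without BAPN replicate 1, and -3.49 and -2.16 without BAPN replicate 3.

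With BAPN replicate 2 recovered from the deposited mean, an alternative chosen after seeing the data that gave 3 libraries, 1086 genes passed, 308 higher and 778 lower. In that fit Ucp1 fell from 3550 ± 1110 (SD, n = 4) to 201 ± 223 (SD, n = 3), with a log2FC of -4.94 ± 0.80 and a limma adjusted p of 0.0207. Gys2 (-3.34), Gk (-3.12), Slc27a2 (-2.91) and Fabp3 (-2.78) fell as well. Thbs1 (2.84 ± 0.36), Lep (2.79), Cthrc1 (2.71), Lox (2.40 ± 0.47, adjusted p = 0.0228), Col8a1 (2.37), Comp (2.28) and Col5a2 (1.96) rose, and several of these encode matrix proteins. In the lists, 12 of 15 brown adipocyte genes and 23 of 26 oxidative phosphorylation genes fell, and 10 of 18 macrophage and 5 of 19 collagen genes rose (adjusted p = 0.53 for each list with an estimated correlation). The medians were 1.48 for cardiomyocytes, 1.04 for nerve, 1.3 for B and plasma cells, 1 for T and NK cells and -0.93 for general adipocytes, and these lists passed camera with the preset correlation alone (adjusted p from 0.595 to 0.656 with an estimated correlation). KEGG's oxidative phosphorylation held 108 of its 188 genes among those that fell (adjusted p = 3.86e-77) and osteoclast differentiation 14 of 95 among those that rose (adjusted p = 3.48e-05), by a one-sided Fisher's exact test. That test takes genes as independent of each other, so these p values overstate the evidence where genes vary together. The 108 include pseudogene entries such as Cox5b-ps and Cox7c-ps1, and the 14 include Csf1r and Tyrobp of the macrophage list. The count without the recovered library was 0 when any 1 vehicle, fasudil or combined library was left out. With the recovered library and without BAPN replicate 1 the count was 18. In the 12 libraries without the recovered one, it was 20 without the filter and 18 without scaling, where the median of all genes lay at 0.43.

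**Figure D4:**
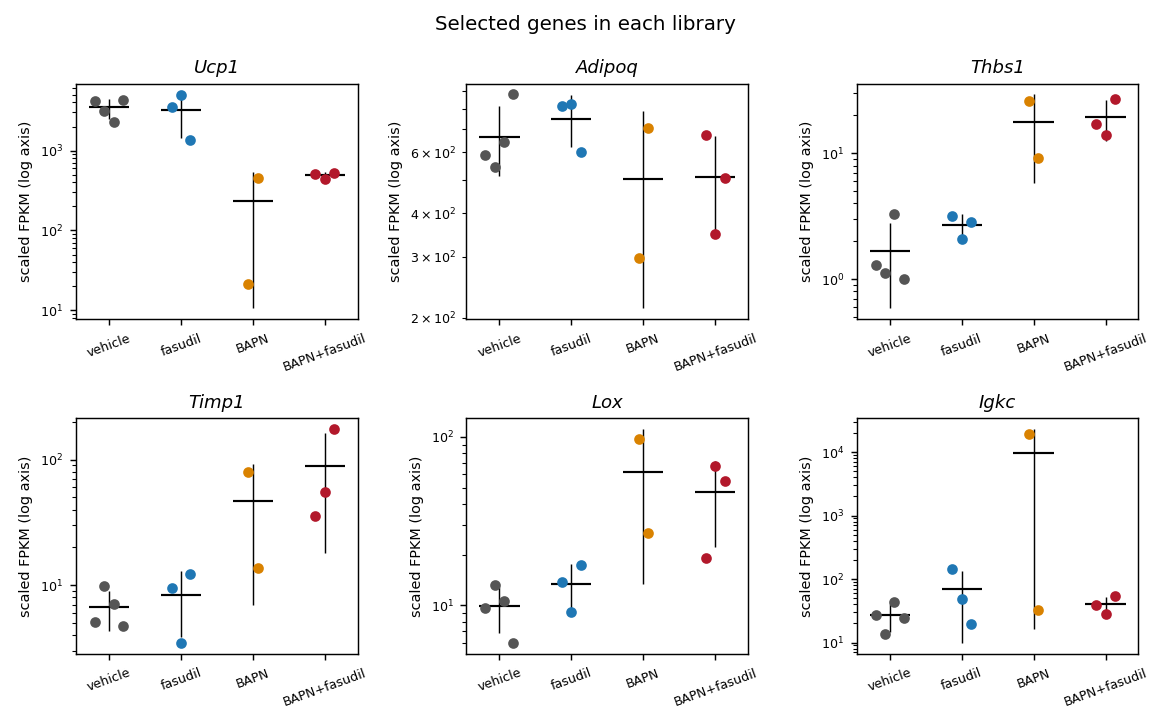
Scaled FPKM (y axis, log scale) of 6 genes in each of the 12 libraries, grouped by treatment (x axis), with 1 point per library, a line for the mean and a whisker for 1 SD, stopped below at 0.5 times the lowest value. Ucp1 lies between 2250 and 4290 with vehicle and between 444 and 524 with the combination, and Igkc reaches 19100 in 1 BAPN library; the genes were chosen after their values were seen.

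Fasudil against vehicle asks what fasudil does alone. Limma called 0 genes, 1098 had an unadjusted p under 0.05, and library quality weights gave 113. Slc35f5 (-0.59 ± 0.10) and Derpc (-0.92 ± 0.16) were among the genes with the smallest p, each with an adjusted p of 0.459. Rock1 was at 12.3 ± 1.21 (SD, n = 4) with vehicle and 7.11 ± 1.2 (SD, n = 3) with fasudil (-0.72 ± 0.16, adjusted p = 0.459, and 0.042 with library quality weights out of a range up to 0.927), and Rock2 had a log2FC of -0.14 ± 0.16 (adjusted p = 0.849), which was 0.06 without scaling. Lox had a log2FC of 0.41 ± 0.50 (adjusted p = 0.857).

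Contractile smooth muscle genes had a median of -0.89 with fasudil alone, and 0 of 22 passed over all genes or over the list alone (camera adjusted p = 0.000717, and adjusted p = 0.965 with an estimated correlation). Myh11, the smooth muscle myosin gene, ranged from 36.8 to 304 in the fasudil libraries and from 136 to 345 in the vehicle libraries (chosen after its values were seen). The median was -0.69 for serum response factor targets and -0.43 for oxidative phosphorylation, 0.49 for cholesterol synthesis and 0.84 for the nerve list, and each of these 4 lists passed camera only with the preset correlation (adjusted p = 0.965 with an estimated correlation). The smooth muscle median was -0.41 without fasudil replicate 2 (camera adjusted p = 0.249) and -1.66 without fasudil replicate 3, and without the latter the oxidative phosphorylation, cholesterol synthesis and nerve lists did not pass camera (medians -0.24, 0.26 and 0.47). The serum response factor targets did not pass without vehicle replicate 2 or 3 or fasudil replicate 1 or 2 (medians -0.55, -0.67, -0.51 and -0.37), nor did the nerve list without vehicle replicate 4 or fasudil replicate 2 (medians 0.69 and 0.74). The brown adipocyte list had a median of -0.40 (camera adjusted p = 0.0188, and adjusted p = 0.965 with an estimated correlation), which was -0.25 without vehicle replicate 4 and -0.03 without fasudil replicate 3 and then did not pass, and the macrophage list one of 0.14. Without fasudil replicate 3 the count of genes was 12, without fasudil replicate 1 it was 2, and with BAPN replicate 2 recovered it was 1.

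The comparison of BAPN with fasudil against BAPN asks what fasudil, begun after 1 week of BAPN alone, adds to BAPN. Limma called 1 gene, Sprr1a, which encodes a small proline-rich protein of the cornified envelope and rose, and 462 had an unadjusted p under 0.05. Sprr1a (ENSMUSG00000050359.8, chromosome 3 at 92391259 to 92393202 in GRCm39) was at 2.83 ± 0.395 (SD, n = 3) with the combination and 0.0499 ± 0.00802 (SD, n = 2) with BAPN, with a log2FC of 1.86 ± 0.19 and an adjusted p of 0.0227. It lies below the minimum level of the naming rule and was named after its values were seen. The predicted gene Gm10217 (-1.55 ± 0.30), among the genes with the next smallest p, had an adjusted p of 1. Lox (-0.29 ± 0.60), Loxl1 (0.11), Loxl2 (-0.27), Loxl3 (-0.01), Rock1 (0.11) and Rock2 (0.19) also had adjusted p values of 1.

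No list held a gene that passed over all genes in this comparison. The brown adipocyte list had a median of 0.51, the macrophage list 0.19, the collagens -0.13 and the elastic fibre genes 0.08 (camera's direction was down), and none of these 4 passed camera. The brown adipocyte value rests on unlike BAPN libraries. Against vehicle its median with BAPN was -1.46 without BAPN replicate 1 and -3.49 without BAPN replicate 3, and with the combination it was -2.09. Over the list alone, 10 of 28 ribosomal protein genes (median 0.47) and 6 of 8 red blood cell genes (median 1.56) were higher, with camera adjusted p values of 4.27e-25 and 8.36e-08 that both became an adjusted p of 0.267 with an estimated correlation. Of the 42 lists tested, 11 passed camera with the preset correlation and 0 with an estimated correlation. The B and plasma cell list had a median of -1.39 and the T and NK cell list one of -0.61, and without BAPN replicate 1 these were 0.21 and 0.49. The count of genes was 0 without any 1 of vehicle replicates 1 to 4, fasudil replicate 2 or replicate 3 of the combined group. It was 15 without the filter and 0 with a pseudocount of 0.1, with library quality weights and with only the compared groups in the fit. Leaving out BAPN replicate 1 or 3 left 1 BAPN library, with no spread of its own. Without replicate 1 or 2 of the combined group the 1 gene called was not Sprr1a, which passed in 3 of the 12 fits that left out a library (log2FC from 1.77 to 1.91), those without fasudil replicate 1 or 3 or BAPN replicate 3.

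BAPN with fasudil against fasudil asks what BAPN adds to fasudil, though the combined group also had BAPN alone for 1 week before fasudil. Limma called 3 genes, and 2712 had an unadjusted p under 0.05. Il3ra (ENSMUSG00000068758.9, chromosome 14 at 8113752 to 8123488), a subunit of the interleukin-3 receptor, rose from 4.32 ± 0.181 (SD, n = 3) to 14.2 ± 3.74 (SD, n = 3), with a log2FC of 1.49 ± 0.16 and an adjusted p of 0.0201. Rap1gap (ENSMUSG00000041351.17, chromosome 4 at 137392037 to 137457172), which inactivates the small GTPase Rap1, fell from 17.7 ± 0.553 (SD, n = 3) to 6.76 ± 0.867 (SD, n = 3), with a log2FC of -1.28 ± 0.16 and an adjusted p of 0.0375. Sprr1a rose by 1.78 ± 0.17 on the log2 scale (adjusted p = 0.0118). Rock1 (0.93 ± 0.17, adjusted p = 0.106), Rock2 (0.68 ± 0.17, adjusted p = 0.149) and Lox (1.60 ± 0.54, adjusted p = 0.19, and 0.00581 with library quality weights out of a range up to 0.351) did not pass, nor did Loxl1 (0.98), Loxl2 (0.95) and Loxl3 (1.43). Of the 12 fits that left out a library, Sprr1a passed in 10, Il3ra in 7 and Rap1gap in 5. All 3 lost the threshold without fasudil replicate 2 or replicate 3 of the combined group, and both Il3ra and Rap1gap without vehicle replicate 1 or 3 or fasudil replicate 1, and Rap1gap without vehicle replicate 4 or replicate 2 of the combined group.

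In the lists no gene passed over all genes. Adjusted over the list alone, 15 of 18 macrophage genes (median 1.43), 10 of 22 genes of TGF-beta and BMP signalling (median 0.86) and 8 of 18 serum response factor targets (median 1.15) were higher, and 6 of 15 brown adipocyte (median -1.19) and 6 of 19 cholesterol synthesis genes (median -0.54) were lower. All 5 lists passed camera with the preset correlation and had an adjusted p of 0.413 with an estimated correlation. In all, 25 of 42 lists passed camera, 20 up and 5 down, and 0 with an estimated correlation. Among them were contractile smooth muscle (median 1.29, and 2 without fasudil replicate 3), collagens (1.65, and 0.96 and 2.25 without fasudil replicates 2 and 3), elastic fibre (1.26), matrix glycoproteins (1.27, and 1.91 without replicate 1 of the combined group) and red blood cells (1.75, and 1.08 without fasudil replicate 3). Their adjusted p values were 0.51 for smooth muscle and 0.413 for the other 4 with an estimated correlation. The count of genes was 88 without fasudil replicate 3, 6 without replicate 1 of the combined group, 5 without vehicle replicate 2 or 4, 1 without vehicle replicate 1 or 3, and 0 without fasudil replicate 2 or replicate 3 of the combined group. With BAPN replicate 2 recovered it was 24, with Thbs1 (2.41), Hbb-bt (2.15) and Pgf (1.85) among those that rose and Ehhadh (-2.06) and Fbp2 (-1.50) among those that fell, and with library quality weights it was 4388.

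The interaction asks whether the combination departs from the sum of the single treatments on the log2 scale. Only the combined group had BAPN alone for 1 week before fasudil, so drug and schedule cannot be told apart here. Limma called 1 of 13748 genes, and 724 had an unadjusted p under 0.05. The interaction values for Lox (-0.71), Loxl1 (0.31), Loxl2 (-0.18), Loxl3 (0.48), Rock1 (0.83) and Rock2 (0.33) had adjusted p values of at least 0.837. Of the 42 lists, 14 passed camera with the preset correlation and 0 with an estimated correlation. The count was 0 without any 1 of vehicle replicates 1, 3 and 4, fasudil replicates 2 and 3 and replicate 2 of the combined group. Leaving out BAPN replicate 1 or 3 left 1 BAPN library, with no spread of its own. Without fasudil replicate 1 or replicate 1 of the combined group 1 gene was called, a different gene. The count was 0 with upper-quartile scaling, without scaling and with library quality weights, 2 with a pseudocount of 5 and 11 without the filter.

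Across the 13748 genes, which are not independent replicates, the log2FC of fasudil without BAPN and that with BAPN had a Pearson r of -0.17 and a Spearman correlation of -0.15, and 44.4% of the genes had the same sign in both. These 2 comparisons share no library. Pearson's r was 0.25 without BAPN replicate 1, 0.01 without replicate 2 of the combined group, and -0.33 without BAPN replicate 3 or replicate 1 of the combined group. The log2FC of BAPN without fasudil and that with fasudil had an r of 0.47 and a Spearman correlation of 0.51, with the same sign in 69.2% of the genes, and r lay between 0.35 and 0.53 when each library was left out.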

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

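All tests of explanations in this part were chosen after the results were seen, except the counts of other splits of the samples without the recovered library.

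In the vehicle group, 11 of 183 values checked lay far from the other 3 libraries, and chance gives about 5%. Of these, 8 were in vehicle replicate 3, in scaled FPKM with the nearest other library in parentheses: Scgb1a1 at 6750 (2.97), Ltf at 864 (1.45), Lyz2 at 535 (78.4), Myl4 at 21.2 (5.86), Thbs1 at 3.32 (1.29), Elovl6 at 30.7 (71.3), Agpat2 at 534 (854) and Rhoa at 135 (146). The other 3 were in vehicle replicate 2, where Pcolce was at 88.6 (50.2), Dbh at 3.54 (0.309) and the mean log2 value of the T and NK cell list at 0.54 (0.78). In the BAPN columns, which include 1 that was not analysed as deposited, the authors' group mean differed from the mean of the deposited columns in 28495 genes. A further 14 lists passed the interaction test only with camera's preset correlation, and 0 with an estimated correlation, and are not listed singly.

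Brown adipocyte genes had a median log2FC of -2.09 with BAPN and fasudil against vehicle over a list of 15 genes, of which 3 fell, 3 are also in another list and 15 are at 1 FPKM or more with vehicle. Less fat of every kind, if it lowered both fat lists alike, would leave the brown list minus the general adipocyte list unchanged. That difference changed by -0.91 between the groups (SD 0.3 and 0.11). Its two-sided exact permutation p of 0.0286 was the lowest that 35 splits can give. Fasudil replicate 3, given no BAPN, lay at -2.9, below replicate 2 of the combined group at -2.46. The difference thus also varied without BAPN, so less fat of every kind was not excluded. Scaling of the libraries was argued against, since the median was -1.72 without scaling. Among the 35 splits of the 7 libraries, 1, the real one, gave as many genes as the 231 called, and the highest other gave 1. This argues against chance for that count, but so few splits cannot exclude it. The other splits also mix the groups, which widens the spread within each and lowers their counts. An effect of the treatment, less fat of every kind and a different share of brown fat in the dissected samples all stay open. The design gives no value that separates them.

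Macrophage genes had a median log2FC of 1.41 with BAPN and fasudil against vehicle over 18 genes, of which 7 rose, 4 are also in another list and 17 are at 1 FPKM or more with vehicle. A lower share of fat cells, which raises every other cell type alike, stays open: macrophage minus smooth muscle and endothelium genes differed by 1.13 between the groups (two-sided exact permutation p = 0.0571; SD 1.05 and 0.16). Blood left in the samples also stays open, since neutrophil genes differed by 0.85 (two-sided exact permutation p = 0.257, SD 1.21 and 0.49) and red blood cell genes had a median of 1.79. The neutrophil mean was 3.46 in replicate 1 of the combined group, 1.32 and 1.41 in its replicates 2 and 3, and 0.81 to 1.82 with vehicle. Haemoglobin took 1.35%, 3.12% and 3.45% of the FPKM in combined replicates 1 to 3, where macrophage genes were at 5.27, 3.88 and 4.63. Neutrophil and haemoglobin genes thus did not run together. For the lists as a whole, 6 of the 35 splits gave at least the 23 lists passing camera, and the highest other gave 27, so chance was not excluded. An effect of the treatment stays open and was not tested apart from these.

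Immunoglobulin genes were high in BAPN replicate 1, where Igkc was at 19100 scaled FPKM against at most 143 in the other libraries. Lymphoid tissue in that sample is a candidate explanation: T and NK cell genes were 1.03 log2 units above the highest other library, at 3.08 against 2.05 in replicate 1 of BAPN with fasudil. The bounds of 1 log2 unit here were set after the values were seen, and that list has 13 tested genes, 4 of them at 1 FPKM or more with vehicle and 0 shared with another list. An effect of BAPN shared by the libraries given it is argued against: the mean log2 value of 78 immunoglobulin genes was at most 0.75 in the other 4, 0.11 above the highest vehicle library, against 6.19 in BAPN replicate 1. A response in that 1 sample alone stays open and was not tested.

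In fasudil against vehicle limma called 0 genes (1098 at an unadjusted p under 0.05, and 113 genes with library quality weights), which 35 of 35 splits must reach, so their count tests nothing there (highest other 1). Of its splits, 29 of 35 gave at least the 9 lists that passed camera (highest other 21), so chance was not excluded for the lists. With BAPN replicate 2 recovered, 1 of 35 splits gave the 1086 genes of BAPN against vehicle and the highest other gave 1. This argues against chance but cannot exclude it, and that fit was chosen after its count was seen. The other splits mix the groups here as well, which lowers their counts, and the 1086 depended on BAPN replicate 1, as given above. For BAPN with fasudil against fasudil, the 10 splits are too few for a share under 0.05: 2 gave at least the 3 genes called, with 665 in the highest other, and 1 gave the 25 lists, with 22 in the highest other. The split with 665 genes set fasudil replicates 1 and 2 and replicate 1 of the combined group against the rest. In these libraries Eln was at 133, 98.2 and 286 scaled FPKM and Myh11 at 50.8, 36.8 and 118. In fasudil replicate 3 and replicates 2 and 3 of the combined group, Eln was at 1490, 4650 and 2360 and Myh11 at 304, 515 and 285. Both genes were chosen after their values were seen, and what separates these libraries was not tested.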

How the results depend on the processing

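The alternatives with BAPN replicate 2 recovered, without scaling, with pseudocounts of 0.1 and 5, and with BAPN replicate 1 and replicate 1 of the combined group left out together were chosen after seeing the data, the recovered library and no scaling after their counts had been seen.

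The 24 genes named for BAPN with fasudil against vehicle kept their direction in the 26 other settings. This says little, because the naming rule took only genes whose groups do not overlap. All 24 passed with both other scalings, no scaling, the stricter filter, library quality weights, only the compared groups, a prior variance that was not robust and the recovered library. With a pseudocount of 0.1, 23 passed, with one of 5 it was 22, without the filter 2 and with a replicate block 0.

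The count of 231 genes for BAPN with fasudil against vehicle was 419 with upper-quartile scaling, 12 without the filter, 453 with at least 1 FPKM in 3 libraries, 5201 with library quality weights, 1753 with only the compared groups, 423 with a prior variance that was not robust, 0 with a replicate block, 961 with the recovered library, 1898 with it and without BAPN replicate 1, 1680 without scaling, 1452 with both replicates 1 left out, and 150 with an absolute log2FC of at least 1, which removes genes by construction. It was 291 with median-of-ratios scaling and with a pseudocount of 0.1, and 306 with a pseudocount of 5. With only the compared groups the scaling and the filter stayed the same, so the change from 231 to 1753 came through the spread shared with the other groups. Apart from that and the minimum log2FC, the cause was not tested for these changes or for those that follow. Without the filter the counts were 15 for BAPN with fasudil against BAPN, 20 for BAPN against vehicle, 1 for fasudil against vehicle, 1 for BAPN with fasudil against fasudil and 11 for the interaction. Library quality weights gave 0, 0, 113, 4388 and 0 in that order. With the recovered library BAPN against vehicle had 1086 genes, fasudil against vehicle 1 and BAPN with fasudil against fasudil 24, and without BAPN replicate 1 as well these were 18, 1 and 33. With only the compared groups BAPN with fasudil had 0 genes against BAPN and 1 against fasudil, and with both replicates 1 left out 0 and 8. BAPN with fasudil against BAPN had 0 genes with a pseudocount of 0.1, and BAPN against vehicle 18 without scaling. The interaction had 0 genes with upper-quartile scaling, without scaling and with both replicates 1 left out, and 2 with a pseudocount of 5. The replicate block gave 0 genes in all 6 comparisons by limma.

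Leaving out each library in turn gave 1 to 1695 genes for BAPN with fasudil against vehicle, 0 to 93 against BAPN and 0 to 88 against fasudil, 0 to 1960 for BAPN against vehicle, 0 to 12 for fasudil against vehicle and 0 to 94 for the interaction. The highest counts against BAPN, for BAPN against vehicle and for the interaction came without BAPN replicate 3. That fit has 1 BAPN library, and a group left with 1 library was assumed to vary like the other groups. The number of lists passing camera over all comparisons, 104, was 99 to 121 in these fits, 0 with an estimated correlation, 15 by fry and 53 by its mixed test. The first component's share was 32.2% to 44.9%.

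The correlation across genes of the fasudil effects, -0.17, ran from -0.33 to 0.25 and was 0.23 with the recovered library and without BAPN replicate 1. That of the BAPN effects, 0.47, ran from 0.35 to 0.53 and was 0.41 with the replicate block, 0.54 with the recovered library and 0.57 with it and without BAPN replicate 1. Lox in BAPN with fasudil against BAPN, -0.29, reversed to 0.07 with library quality weights, 0.03 with the recovered library and without BAPN replicate 1, and 1.08 with both replicates 1 left out, and ran from -1.2 to 0.62 with each library left out. Rock2 in fasudil against vehicle reversed to 0.06 without scaling, and the nerve list in BAPN against vehicle had a median of 1.39 without scaling with camera's direction reversed. With each library left out, list medians that reversed ran from -1.72 to 0.49 for T and NK cells, -2.85 to 0.21 for B and plasma cells, -1.46 to 0.72 for cardiomyocytes and -1.1 to -0.02 for nerve (by camera's direction) in BAPN with fasudil against BAPN. They ran from -0.21 to 1.31 for antigen presentation against fasudil, and in the interaction from -0.15 to 1.45 for oxidative phosphorylation, -1.56 to 0.66 for T and NK cells and -1.82 to 0.16 for cardiomyocytes.

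After each group's mean was subtracted, libraries of the same number were no more alike than others. Over 15 pairs from different groups the correlation of what remained was -0.49 to 0.21 (median -0.03), and over 38 pairs of different numbers -0.46 to 0.49. The numbers were therefore not taken to pair the samples. Of the 66 single-gene results, 48 passed, and of these 48 lost the threshold with the replicate block and 43 without the filter. DESeq2 and voom were not run because the table holds no counts, and leaving out BAPN replicate 2 was not run because it was not in the fit. Depth was estimated and not known, so no limit from it was set on single genes.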

Other observations

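All values in this part were chosen after the results were seen, and no explanation of them was tested.

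Genes of sympathetic neurons differed between libraries within groups. Dbh was at 68.2 scaled FPKM in fasudil replicate 2, 199 in fasudil replicate 3, 132 in BAPN replicate 1, 84 in BAPN with fasudil replicate 1 and 10.1 in its replicate 3, and at most 3.54 elsewhere. Th was at 50, 148, 114, 61.6 and 7.79 in the same libraries and at most 3.28 elsewhere. The nerve list had a median log2 value of 3.61, 4.15, 3.49, 3.53 and 3.02 in them and of 0.67 to 2.01 in the others.

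Genes of other tissues also differed within groups. The cardiomyocyte list had its highest medians in fasudil replicate 1 (4.58) and BAPN replicate 1 (4.24), where Tnnt2 was at 61.3 and 44.5 scaled FPKM, against at most 24.1 elsewhere. The skeletal muscle list ranged from 0.23 to 5.46. The epithelium list had a median of 3.44 in vehicle replicate 3, and Scgb1a1, at 6750 in that library, was at 145 in BAPN with fasudil replicate 2. The B and plasma cell list had a median of 4.8 in BAPN replicate 1 and at most 1.82 elsewhere.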
